A study of Ciona robusta with 9 samples.

How the data were processed

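Gene expression was measured by RNA sequencing in whole embryos of the ascidian Ciona robusta, a sea squirt whose tadpole larva has a notochord, a dorsal nerve cord and tail muscle. Fertilized eggs received a plasmid by electroporation and grew in artificial seawater at 21 °C. Per the labels' protocols, 400 embryos per sample were collected at Hotta stage 19.5 and libraries were made with a stranded mRNA kit. The control plasmid joined regulatory DNA of Bra (Brachyury, the T-box transcription factor of the notochord) to GFP. Both other plasmids carried a Venus-Bra fusion, under regulatory DNA of either Etr1 or Tbx6-r.b. There were 3 groups with 3 libraries each, and the submitters describe the replicates as biological. Beyond that word, the labels do not say whether the replicates came from separate fertilizations, so p-values measure the spread between these samples.

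The authors deposited 2 tables with the same 15284 gene models, 1 per Bra construct, each holding the 3 control libraries and 3 construct libraries. Per the file headers, the deposited values are counts normalized to library size, a signal that is never negative, beside regularized log2 values. TopHat2 2.9.8b and DESeq 1.8.1 are named per the submitters' processing notes. The counting program, its strand setting and the genome build are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be told apart.

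Within each library, all deposited normalized values were whole multiples of the smallest one (100% of values, tolerance 0.01), so whole read counts were recovered. Median-of-ratios size factors recomputed from these reads matched the deposited scaling to a relative difference of 4.3e-10. The control reads were identical in both tables, with 0 values differing. Recovered totals ran from 9043181 to 10399304 reads per library. No library was a copy of another: the chi-square per gene between replicates lay between 11.59 and 36.17, where sampling noise alone gives about 1.

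The tables pair no names with their KH gene IDs, and the gene table supplied for the species (21486 genes) matched 0 of them. None of the 13 gene lists fixed before the data were examined (notochord, nervous system, muscle and others) could therefore be matched or tested, and the planned camera and fry tests were not run. By the rule fixed at the same time, at most 2 IDs that rose and 2 that fell are printed per comparison, taken by largest log2 change among called genes with a mean of at least 1 CPM and no overlap between groups. The plan also listed IDs held beforehand for a few genes: KH.S1404 for Bra, KH.C6.128 for Etr1, KH.S654 for Tbx6-r.b, KH.C14.307 for Mrf and KH.C11.313 for Foxa.a. These names are an assumption that neither the deposited tables nor the gene table could check, and the IDs are used throughout. KH.S1404 and KH.S654 each covered several models, and the model with the highest mean count was taken. Such models may be separate genes on the same scaffold, so the one taken need not be the named gene.

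Each construct was compared with control within its own table by limma 3.58.1 (R 4.3.3) with an intensity trend, on log2(normalized count + 1), for genes with a mean normalized count of at least 10. Calls had a two-sided Benjamini-Hochberg adjusted p under 0.05. A fold change on this scale understates the change of low genes. The plan had assumed raw counts and the edgeR quasi-likelihood test. Because the deposited values are normalized, that test was run as an alternative on the recovered reads (edgeR 4.0.16), as was the DESeq2 Wald test (1.42.0). It called 14 genes with Etr1>Bra, 70 with Tbx6-r.b>Bra and 0 between the constructs. The constructs were compared with each other on recovered reads rescaled together by median of ratios, because the tables had been normalized separately. Intervals of read ratios are exact 95% binomial intervals and cover counting error only.

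Libraries of different groups share replicate numbers in their titles, and the data were checked for pairing before calls were compared. Over 11494 genes, deviations from the group means correlated at 0.48 to 0.72 between libraries of the same number. Between different numbers they correlated at −0.1 or less. Deviations within a group sum to 0, so negative values there follow from the positive ones and are no separate evidence. The numbers were therefore taken to pair the samples, and fits with the replicate number as a block are given beside the unblocked results. Those fits leave 2 residual degrees of freedom per gene, and for the comparisons that involve Tbx6-r.b>Bra limma shared a common spread over all genes at each expression level. With all pairs, every blocked limma p-value of those comparisons, small or not, rests on that shared spread. The spread of the single gene between pairs does not enter it.

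Each procedure was tested on simulated reads with 200 changed genes per comparison. Without the block, limma recovered 80.3% of 4-fold, 29.9% of 2-fold and 1.49% of 1.5-fold changes for Etr1>Bra against control (11507 genes). The shares were 81.8%, 26.9% and 1.49% for Tbx6-r.b>Bra (11479 genes), and 86.4%, 34.3% and 2.99% between constructs (11464 genes), with 0 false calls in each. With the block, 2-fold recovery was 82.1%, 76.1% and 77.6% in that order, and 7.93%, 2.92% and 3.97% of the calls were false. Each simulated change had the same size in every pair, whereas changes in the data differed between pairs. These rates therefore do not cover changes that vary between pairs. Alternatives covered the test, scaling, filter, pseudocount, block and left-out libraries. Unchanged groups with shared controls were simulated 100 times, with all libraries, the controls included, drawn anew.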

Results

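Expression was measured in 9 whole-embryo libraries of Ciona robusta: 3 with the control plasmid Bra>GFP, 3 with Etr1>Bra and 3 with Tbx6-r.b>Bra. The Bra constructs were designed to express Bra, a notochord transcription factor, outside its usual tissue. Etr1 regulatory DNA is used to reach the nervous system, and Tbx6-r.b regulatory DNA the tail muscle. Control libraries held 9533464, 10222725 and 9804657 gene-assigned reads. Etr1>Bra libraries held 10399304, 9610478 and 9913750, and Tbx6-r.b>Bra libraries 9286834, 9043181 and 9261765. Between 10.6% and 13.3% of the reads of a library fell on its 10 most abundant genes. Values below are normalized read counts as mean ± SD with n = 3 per group, and log2 changes carry their standard error. Adjusted p-values come from limma with Benjamini-Hochberg adjustment over all genes tested, and their ranges over the alternatives cover settings that leave out no library.

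The expressed gene was examined first. KH.S1404.1, taken here as Bra, stood at 338.3 ± 29.4 normalized counts in control and 491.3 ± 67.4 with Etr1>Bra (replicates 481, 430 and 563). The log2 change was 0.53 ± 0.15, with all 3 Etr1>Bra libraries above all 3 controls, and it did not pass the test over all genes (limma adjusted p = 0.287). With the replicate number as a block it did (adjusted p = 0.0436, range over the alternatives 0.0432 to 0.387). With Tbx6-r.b>Bra the level was 386.8 ± 75.5 against 334.9 ± 29.0 in control, a log2 change of 0.19 ± 0.17 (95% interval −0.18 to 0.57) that did not pass the test (adjusted p of 0.845 to 1 over the alternatives). The endogenous transcript is counted together with any reads of the transgene's coding sequence, so this level does not separate them.

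The genes whose regulatory DNA drove the constructs were examined next. KH.C6.128, taken as the neural gene Etr1, stood at 3950 ± 51.5 in control and 2610 ± 1180 with Etr1>Bra. Its log2 change of −0.71 ± 0.30 did not pass the test (adjusted p = 0.69, and 0.0849 with the block, range over the alternatives 0.02 to 0.937). It passed in the blocked fit of all 9 libraries (0.02) and in the block without replicate 1 (4.85e-15). Its replicates were far apart at 3790, 2610 and 1430. With Tbx6-r.b>Bra it was at 3936 ± 501 against 3911 ± 51.1 in control. Of the 5 models under KH.S654, the ID held for Tbx6-r.b, KH.S654.5 was the most abundant. It stood at 1550 ± 66.4 in control and 1550 ± 189 with Etr1>Bra, and at 1594 ± 173 with Tbx6-r.b>Bra. The control means of KH.S654.1 to KH.S654.4 in the Etr1>Bra comparison were 1.61, 0.976, 11.7 and 567. These models may be separate genes on the same scaffold. None could be matched to Tbx6-r.b, so the level of that gene is not known here. KH.C11.313, taken as Foxa.a, a forkhead factor of the notochord and endoderm, was 1.60 times its control mean with Etr1>Bra. Its log2 change of 0.68 ± 0.14 did not pass in limma without the block (adjusted p = 0.129). It passed with the block (0.00296) and in DESeq2 without it (0.00244), with a range over the alternatives of 4.77e-06 to 0.284. The blocked call was lost without replicate 2 (adjusted p = 0.13). With Tbx6-r.b>Bra its log2 change was 0.34 ± 0.19, not past the test (adjusted p = 1, and 0.154 with the block) except in the block without replicate 3 (0.00316). KH.C14.307, taken as the muscle regulator Mrf, changed by 0.10 ± 0.16 with Etr1>Bra and −0.39 ± 0.17 with Tbx6-r.b>Bra, neither past the test with or without the block.

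**Figure D1:**
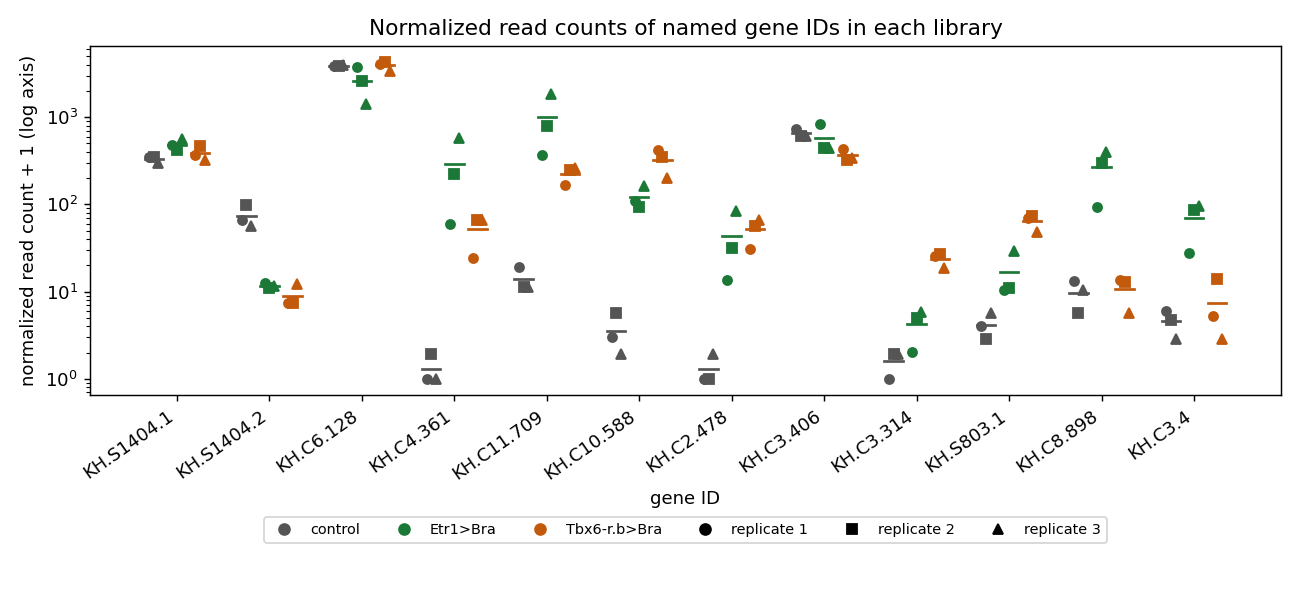
Normalized read count + 1 (log axis) of named gene IDs in each of the 9 libraries, scaled together by median of ratios, with 1 point per library, its shape giving the replicate number, and a line at each group mean. KH.C4.361 and KH.C2.478 had 1 read each over the 3 control libraries and over 100 reads with each construct.

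Etr1>Bra against control asked which transcripts change with a plasmid that places Bra under Etr1 regulatory DNA. The control plasmid differs from it in regulatory DNA and in carrying GFP in place of Venus-Bra. No group had Etr1 or Tbx6-r.b regulatory DNA without Bra, so a change against control cannot be credited to Bra alone. Most of the change was gain of expression: 15 genes rose and 1 fell among 11514 tested, and 7 of the 15 had a control mean under 10. The median log2 change of the risen genes was 4.02. KH.C4.361 went from 0.3168 ± 0.549 to 291.3 ± 270, a log2 change of 7.33 ± 0.77 (adjusted p = 0.0157). Its reads were 1 in all controls and 874 with Etr1>Bra, a ratio of 912 with a counting interval of 163 to 36100. KH.C11.709 rose from 13.15 ± 4.68 to 1014 ± 764, a log2 change of 5.92 ± 0.51 (adjusted p = 0.0126). The only gene that fell was KH.S1404.2, which shares the scaffold part of its ID with KH.S1404.1. It went from 73.62 ± 21.7 to 10.87 ± 0.782, a log2 change of −2.62 ± 0.32 (adjusted p = 0.022). All 3 genes kept their direction in every pair, which follows from the rule that named only genes without overlap between groups.

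With the replicate number as a block, 447 genes were called, 402 higher and 45 lower. Of the 402, 247 were at least 2-fold higher, 73 had a control mean under 10 and 200 had one over 100. The 45 lower genes had a median log2 change of −0.85. The unblocked count changed when single libraries were left out. It was 170 without Etr1>Bra replicate 1, 0 without Etr1>Bra replicate 2, and 5, 2 and 1 without control replicate 1, 2 or 3. Without Etr1>Bra replicate 2, 848 genes had an unadjusted limma p under 0.05, against 750 with all libraries. KH.C4.361 kept a log2 change of 7.235 there, so a lost call need not mean a lost change. KH.C4.361 and KH.S1404.2 were not past the threshold without Etr1>Bra replicate 2 (adjusted p = 0.229 and 0.222) or without any of the controls (adjusted p of 0.0598 to 0.164), and KH.C11.709 was not without Etr1>Bra replicate 2 or control replicate 3 (0.165 and 0.0507). All 3 calls were lost with the regularized log2 values (adjusted p of 0.112 to 0.3) and in the block without replicate 2 (0.0667 to 0.13). The blocked count was 1233 without replicate 1 and 8 without replicate 2.

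Tbx6-r.b>Bra against control asked the same for Tbx6-r.b regulatory DNA, with the same limit of the control plasmid. Here 58 genes rose and 3 fell among 11445 tested, and 21 of the 58 had a control mean under 10. The median log2 change of the risen genes was 2.51. KH.C10.588 rose from 2.560 ± 1.93 to 322.1 ± 112, a log2 change of 6.58 ± 0.44 (adjusted p = 0.000114). KH.C2.478 rose from 0.3132 ± 0.543 to 50.81 ± 19.0, a log2 change of 5.30 ± 0.60 (adjusted p = 0.00292), on 1 control read against 151, a ratio of 160 with a counting interval of 28.2 to 6350. Of the 3 that fell, KH.S1404.2 went from 72.87 ± 21.4 to 8.023 ± 2.76, a log2 change of −3.04 ± 0.36 (adjusted p = 0.00362). KH.C3.406 went from 742, 604 and 616 in the control libraries to 364.2 ± 53.8, a log2 change of −0.85 ± 0.16 (adjusted p = 0.0471). The latter call was lost with scaling by TMM (adjusted p = 0.0502), with the regularized log2 values (0.0517), in the unblocked fit of all 9 libraries (0.392) and without each of 5 of the libraries in turn (adjusted p up to 0.286).

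With the replicate number as a block, 446 genes were called, 341 higher and 105 lower. Of the 341, 187 were at least 2-fold higher and 71 had a control mean under 10, while 9 of the 105 were at least 2-fold lower. The unblocked count of 61 was 94 without Tbx6-r.b>Bra replicate 1, 14 without replicate 2, 14 without replicate 3 and 34 without control replicate 2. KH.C2.478 was not called without Tbx6-r.b>Bra replicate 2 or 3 (adjusted p = 0.0974 and 0.111). The blocked count was 270 without replicate 1 and 296 without replicate 2.

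Many genes rose with both constructs. Among 11388 genes tested in both comparisons, 14 rose with Etr1>Bra, 56 with Tbx6-r.b>Bra and 9 with both, where independent lists of these sizes would share 0.0688 (exact one-sided hypergeometric p = 1.7e-18). KH.C4.361 also rose with Tbx6-r.b>Bra, by 5.26 ± 0.64 (adjusted p = 0.00396), and KH.C11.709 by 4.03 ± 0.30 (adjusted p = 0.000155). KH.C10.588 also rose with Etr1>Bra, by 5.19 ± 0.48 (adjusted p = 0.0126). KH.C2.478 had a log2 change of 4.75 ± 0.81 there, past the threshold with the block only (adjusted p = 0.0752, and 0.00113 with the block). With the block, 189 genes rose with both, of 378 and 336, where independent lists would share 11.2. These are the genes tested in both comparisons, out of 402 and 341 risen genes. A gene that was low in control and rose with 1 construct could fall under the filter of the other comparison. KH.C8.898 and KH.C3.4 were thus not tested with Tbx6-r.b>Bra, nor KH.C3.314 and KH.S803.1 with Etr1>Bra. All of these are left out of the overlap. With the block, 45 genes fell with Etr1>Bra, 105 with Tbx6-r.b>Bra and 1 with both, KH.S1404.2, where independent lists would share 0.415 (exact one-sided hypergeometric p = 0.34). Few shared calls do not mean opposite changes. Of the 105, 100 also had a negative log2 change with Etr1>Bra, and of the 45, 33 had one with Tbx6-r.b>Bra. The shared controls favour the same direction, so these shares are no test. The number of shared falls was 18 in the block without replicate 1, 0 without replicate 2 and 4 without replicate 3.

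Both comparisons used the same 3 controls, which alone makes their changes alike. Over all 11388 genes the log2 changes correlated at 0.78 across genes, which are not independent replicates. Simulated unchanged groups that shared simulated controls gave 0.50 on average (0.475 to 0.533 in 100 draws). The controls were drawn anew each time, so the simulations do not carry deviations of the real controls. The covariance was 0.125 against a simulated 0.0229, a difference of 0.102. The share of genes changed in the same direction was 73.4% against 66.6%. The simulations gave 0 shared rises without the block and 0.02 on average with it. The 3 controls are too few to be split, so part of the excess may come from them. The unblocked number of shared genes, 10 in both directions together, was 0 without Etr1>Bra replicate 2 and 39 without Etr1>Bra replicate 1. It was 3, 2 and 1 without control replicate 1, 2 or 3, and 5 and 4 without Tbx6-r.b>Bra replicate 2 or 3. The blocked number of 190 was 7 without replicate 2.

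**Figure D2:**
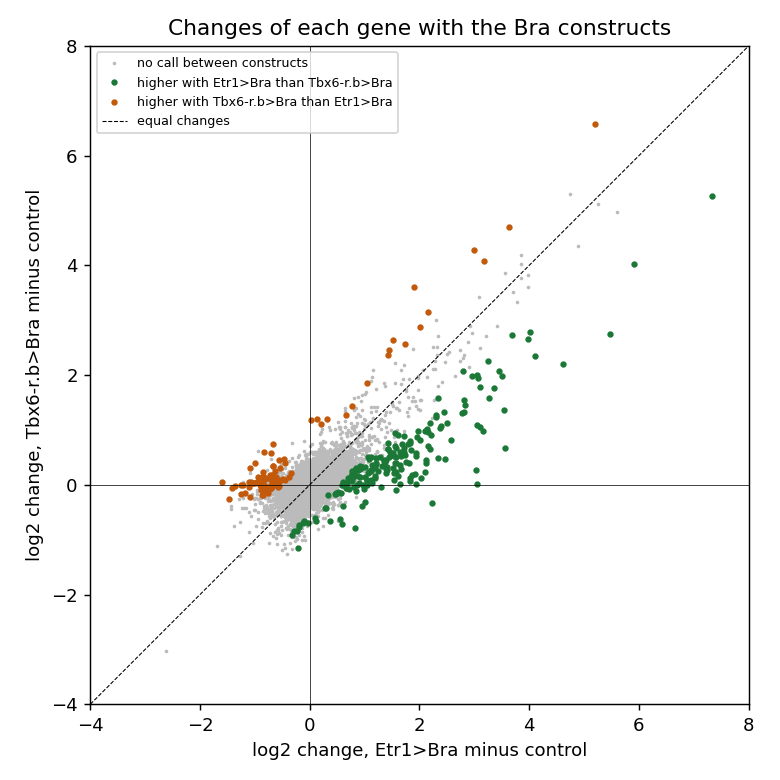
Log2 change against control with Etr1>Bra (horizontal axis) and Tbx6-r.b>Bra (vertical axis) for the 11388 genes tested in both, 1 point per gene, with the line of equal changes dashed. Colours mark genes called between the constructs with the replicate block: 192 of the plotted genes were higher with Etr1>Bra and 99 higher with Tbx6-r.b>Bra.

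The constructs were then compared directly, without the controls. Without the block, limma called 0 of 11514 genes (smallest adjusted p = 0.0766), while 350 had an unadjusted p under 0.05, 101 of them higher with Tbx6-r.b>Bra and 249 higher with Etr1>Bra. The edgeR test also called 0, and DESeq2 called 39. With the replicate number as a block limma called 312 genes, 101 higher with Tbx6-r.b>Bra and 211 higher with Etr1>Bra. The blocked edgeR test called 297, of which 286 were among the 312, and the blocked DESeq2 test 52, all among them. KH.C8.898 stood at 260.3 ± 154 with Etr1>Bra and 9.626 ± 4.37 with Tbx6-r.b>Bra, a log2 difference of −4.48 (blocked adjusted p = 4.43e-63, range over the alternatives 4.43e-63 to 0.0968). Against control it rose with Etr1>Bra by 4.61 ± 0.55 (adjusted p = 0.022). With Tbx6-r.b>Bra its reads were 1.10 times control, with a counting interval of 0.623 to 1.93. KH.C3.4 stood at 68.27 ± 36.2 with Etr1>Bra and 6.278 ± 5.78 with Tbx6-r.b>Bra, a log2 difference of −3.37 (blocked adjusted p = 8.18e-19, range 6.8e-19 to 0.65).

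In the other direction, KH.C3.314 stood at 22.38 ± 4.31 with Tbx6-r.b>Bra and 3.244 ± 1.96 with Etr1>Bra, a log2 difference of 2.58 (blocked adjusted p = 3.1e-06, range over the alternatives 1.44e-06 to 0.949). KH.S803.1 stood at 62.82 ± 13.9 and 15.61 ± 10.5, a log2 difference of 2.09 (blocked adjusted p = 7.16e-10, range 7.16e-10 to 0.823). KH.C6.128, taken as Etr1, was lower with Etr1>Bra than with Tbx6-r.b>Bra, by a log2 difference of 0.72 (blocked adjusted p = 0.000552, range 0.000534 to 1). Its differences in pairs 1, 2 and 3 were 0.13, 0.74 and 1.27, a spread that this blocked p-value does not use. KH.S1404.1, taken as Bra, was not called between the constructs (log2 difference −0.33 ± 0.19, adjusted p of 0.525 to 1 over the alternatives). Of the 211 genes higher with Etr1>Bra, 161 had risen with it against control, and 57 had risen with Tbx6-r.b>Bra. Of the 101 higher with Tbx6-r.b>Bra, 20 had risen with it against control and 32 had fallen with Etr1>Bra. Of 213 genes called as risen with Etr1>Bra alone, 104 differed between the constructs, and of 152 called with Tbx6-r.b>Bra alone, 10 did. Both sets include genes under the filter of the other comparison, which were not tested there. For the genes of these sets not called between the constructs, a difference was not shown. These counts depend on the pairs: 203 genes were called without replicate 1, 0 without replicate 2 (1858 at an unadjusted p under 0.05) and 61 without replicate 3. KH.C6.128 was called without replicate 1 (adjusted p = 0.0364) and not without replicate 2 or 3.

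The change differed in size between the pairs of libraries that share a replicate number. The 341 genes higher with Tbx6-r.b>Bra were chosen without the Etr1>Bra libraries, but against the same controls. Over them, the median log2 change with Etr1>Bra was 0.72 in pair 1, 1.08 in pair 2 and 1.87 in pair 3. With Tbx6-r.b>Bra the medians over these genes were 0.875, 1.34 and 1.03. Over the 402 genes higher with Etr1>Bra, the medians were 0.74, 1.24 and 1.97 with Etr1>Bra, and 0.449, 0.826 and 0.489 with Tbx6-r.b>Bra. Of the 341 genes, 305, 324 and 334 were above control with Etr1>Bra in pairs 1, 2 and 3, and 337, 340 and 326 with Tbx6-r.b>Bra. Both lists were called against the shared controls, so the choice of genes pushes these medians and counts upward with either construct. The values of a construct over its own list follow largely from that choice.

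**Figure D3:**
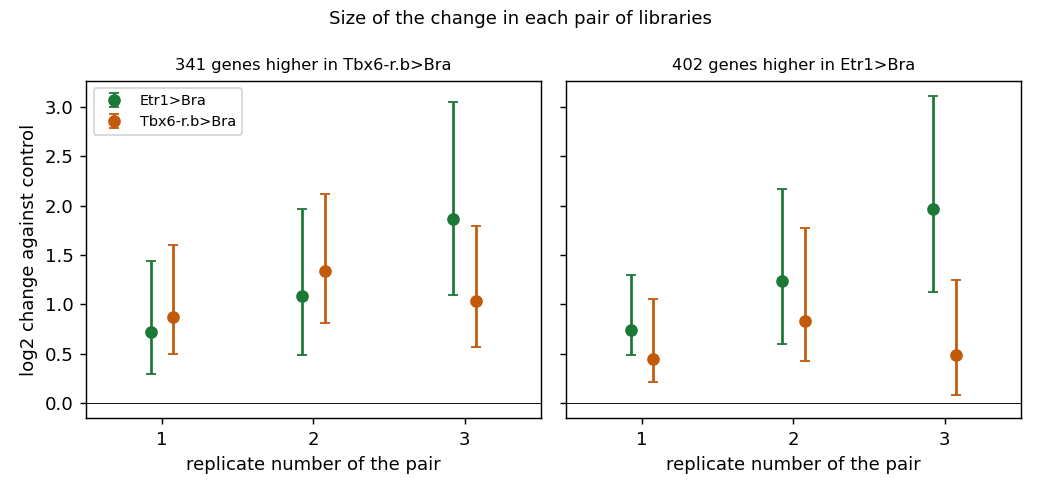
Median log2 change against the control of the same replicate number (points) with the lower and upper quartiles over genes (bars), for each construct and pair, over the 341 genes higher with Tbx6-r.b>Bra (left) and the 402 higher with Etr1>Bra (right) in the blocked fits. With Etr1>Bra the medians of the left panel are 0.72, 1.08 and 1.87.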

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

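Every test of an explanation in this part was chosen after the result was seen, except the counts of other splits of the samples. The tests of depth, of a shared replicate number and of a single response replace earlier versions whose outcomes had been seen, on other gene lists or bounds. For depth, a bound that ignored the direction of the shift had come before, and the values met it in part. The effects of the constructs differed by the blocked limma test between them for 312 genes. The named genes that differed were KH.C8.898 (log2 difference, Tbx6-r.b>Bra minus Etr1>Bra, −4.48), KH.C3.4 (−3.37), KH.C4.361 (−2.05), KH.C11.709 (−1.88), KH.C3.406 (−0.60), KH.C3.314 (2.58), KH.S803.1 (2.09) and KH.C10.588 (1.39). KH.C6.128, taken as Etr1, differed by 0.72. Groups of 3 are too small for a check of outlying samples.

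The difference between constructs leans to 1 side, with 211 of 312 genes higher with Etr1>Bra, and a candidate explanation is a single response that is stronger with Etr1>Bra. Such a response would leave few risen genes higher with Tbx6-r.b>Bra. It was tested on 394 genes that rose in the mean of both constructs in the blocked fit of all 9 libraries, a choice that favours neither construct. Of these, 139 were higher with Etr1>Bra and 13 higher with Tbx6-r.b>Bra, adjusted over these genes. That is 8.55% of the 152 calls, with an exact 95% interval of 4.63% to 14.2%. The threshold allows 5% of false calls in both directions together, so 2.5% on 1 side, and the interval lies above 2.5%. The share depends on the pairs: it was 12 of 252 calls without replicate 1 (interval 2.48% to 8.17%), 1 of 7 without replicate 2 (0.361% to 57.9%) and 41 of 101 without replicate 3 (30.9% to 50.8%). Single genes went both ways. KH.C8.898 was 30.3 times its control mean with Etr1>Bra and 1.11 times with Tbx6-r.b>Bra. KH.C10.588 rose with both and was higher with Tbx6-r.b>Bra in all 3 pairs. Both genes were named for large changes in these same libraries, so they are examples and not evidence on the set. Of the 189 genes risen with both in the blocked fits, 57 were higher with Etr1>Bra and 10 higher with Tbx6-r.b>Bra. The values with all pairs lean against a single response for the set, but it stays open, because the interval reaches 2.5% or less without replicate 1 or 2 and the calls, made on the same 3 pairs, are not independent. So does the biological difference that the design names, the tissue in which Bra was to be expressed, which was not tested.

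The size of the response to Etr1>Bra differed between pairs, with the largest median change over the 402 genes higher with it, 1.97, in pair 3. The tables argue against an effect of the replicate number common to both constructs. Over the 394 genes risen in the mean of both, the step from pair 1 to pair 3 was larger with Etr1>Bra than with Tbx6-r.b>Bra by a median of 1.13 on the log2 scale (quartiles 0.69 and 1.70), a difference in which the controls nearly cancel. Over the 341 genes higher with Tbx6-r.b>Bra the median was 1.12 (quartiles 0.56 and 1.69). They also argue against a shift of all genes alike by sequencing depth, for which the values had already been scaled. Other effects of depth were not tested. If left uncorrected, the depths of these libraries and their controls would shift the step with Etr1>Bra by −0.11 on the log2 scale by total reads and by −0.03 by size factors, so against its direction. The step was 1.17 at the median of the 341 genes, with a lower quartile of 0.49. Over the 110 of them with a control mean over 100 it was 0.70, with a lower quartile of 0.07, which is above both shifts but under 0.11, their largest size without the sign. What stays open is a response of the whole gene set that was stronger in that sample. Of the 341 genes, 86.5% changed more with Etr1>Bra in pair 3 than in pair 1, against 59.5% with Tbx6-r.b>Bra itself. A larger share of embryos or cells that took up the plasmid could give this, and so could a difference in stage within the sample, and no value here separates them.

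KH.S1404.2 fell to about the same level with both constructs, and was the only gene called lower with both in the limma fits of log2 normalized counts to all 6 libraries of each table, with and without the block. The blocks without replicate 1 and without replicate 3 called 18 and 4 genes lower with both. A candidate technical explanation is that part of its control reads came from the control plasmid, which carries Bra regulatory DNA that the labels of both Bra plasmids do not name. The remaining level would then be alike with both constructs: the read ratio of Tbx6-r.b>Bra to Etr1>Bra was 0.764, with a counting interval of 0.430 to 1.34. A response of the gene to Bra that is complete with either construct gives the same values, and the control plasmid is present in every control library. The explanations cannot be told apart, because the design ties the plasmid to the control group and no genome was at hand to place the gene.

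The 6 libraries of a comparison can be split in 10 ways, too few for a share under 0.05. With Etr1>Bra the real split gave 16 genes and the highest of the others 0, so 1 of 10 splits gave as many. With Tbx6-r.b>Bra the real split gave 61 and the highest other 0, again 1 of 10. Between the constructs the real split gave 0, as did each of the others, so 10 of 10 gave as many. Of the 10 splits, 4 part all 3 pairs and can be blocked, and the others in that set exchange the libraries of 1 pair. With the block, the real split gave 447, 446 and 312 genes in that order, and the highest other 0, 14 and 6. In those other splits an effect of the construct enters with the opposite sign in 1 pair, which itself lowers the count. They therefore do not show how many blocked calls would arise without an effect.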

How the results depend on the processing

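Several alternatives were chosen after the data were seen: TMM scaling of the limma values, the regularized log2 values, other pseudocounts and blocks without 1 pair. So were blocked edgeR, blocked DESeq2 and the blocked 9-library fit. Unblocked edgeR with TMM was the planned main test, and limma took its place once the deposited values were found to be normalized. The tests on gene lists were not run, since no name could be matched. Counts stayed within 1.5 times for 8 of 15 alternatives with Etr1>Bra, 9 of 15 with Tbx6-r.b>Bra, 9 of 14 between constructs and 8 of 15 for the genes shared by both. With the replicate block the counts were 447, 446, 312 and 190 in that order, against 16, 61, 0 and 10. Blocked edgeR gave 433, 443, 297 and 189, blocked DESeq2 362, 213, 52 and 120, and the blocked fit of all 9 libraries 576, 230, 133 and 153. Unblocked, DESeq2 gave 287, 141, 39 and 100. The unblocked fit of all 9 libraries gave 88, 27 and, for the shared genes, 19. The regularized log2 values gave 0 with Etr1>Bra in limma (724 at an unadjusted p under 0.05) and 0 shared. The cause was not tested. Leaving out 1 library gave 0 to 170, 14 to 94, 0 to 72 and 0 to 39 genes. Blocks without 1 pair gave 8 to 1233 (332 without replicate 3), 270 to 483 (296 without replicate 2), 0 to 203 (61 without replicate 3) and 7 to 224 (192 without replicate 3).

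KH.S1404.1 with Etr1>Bra passed in the replicate block (0.53, adjusted p = 0.0436), in blocked edgeR (0.529, 0.0432) and in the blocked 9-library fit (0.533, 0.0436). It ranged from 0.429 to 0.624 without 1 library, and from 0.355 to 0.654 in blocks without 1 pair (called without replicate 1, at 0.587). With Tbx6-r.b>Bra no alternative called it. Signs turned only for values near 0 that no setting called: KH.S654.5 with Etr1>Bra (0.004 in edgeR with DESeq2 size factors, −0.104 to 0.044 without 1 library, −0.138 to 0.073 in blocks without 1 pair, 0.047 without replicate 2) and with Tbx6-r.b>Bra (−0.023 to 0.134 and −0.019 to 0.163), KH.C14.307 with Etr1>Bra (−0.074 to 0.205 and −0.050 to 0.222), and KH.C6.128 with Tbx6-r.b>Bra (−0.002 with TMM scaling, −0.072 to 0.109 and −0.075 to 0.119, −0.041 without replicate 1). Among the genes named in the text, the block changed the limma call against control of KH.S1404.1, KH.C11.313, KH.C2.478 and KH.C3.4 (adjusted p = 0.0592, and 0.0013 with the block), each with Etr1>Bra, and no other. At 9043181 to 10399304 reads per library, a gene with a mean under 10 was not tested.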

Other observations

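The replicate number accounted for more of the variance between the 9 libraries than the construct did, 52.6% against 28.7% of the total over 11494 genes. The labels do not say what a shared number stands for.

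Risen genes had a lower median control level than all genes tested. In the blocked fits, the median control mean of risen genes was 92.4 normalized counts with Etr1>Bra and 41.7 with Tbx6-r.b>Bra, against 197 over all genes tested. Of the 402 and 341 risen genes, 200 and 110 had a control mean over 100. The filter on the mean over both groups admits a gene with a control mean under 10 (73 and 71 of the risen genes) mainly when it rises, so part of this difference comes from the filter. Risen genes outnumbered fallen ones with both constructs, at 89.9% and 76.5% of the calls, while the median log2 change of all genes was −0.018 and −0.015.

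KH.C6.128, taken as Etr1, differed from its control by −0.04, −0.59 and −1.49 on the log2 scale in pairs 1, 2 and 3 with Etr1>Bra, and by 0.08, 0.15 and −0.24 with Tbx6-r.b>Bra. The Etr1>Bra pairs stand in the same order by the median change of the 341 genes higher with Tbx6-r.b>Bra, at 0.72, 1.08 and 1.87. With 3 pairs no relation between the values can be tested. KH.S1404.1, taken as Bra, does not follow that order, at 481, 430 and 563 normalized counts with Etr1>Bra.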
